A study of Mus musculus with 8 samples.

How the data were processed

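Plasmacytoid dendritic cells were sorted from spleens of C57BL/6 mice after tamoxifen. Each sample was a pool of 2 to 3 mice, hybridized to 1 mouse Affymetrix array after 2 rounds of RNA amplification. Per the labels, the null mice carried floxed E2-2 (gene symbol Tcf4) and a tamoxifen-activated Cre recombinase, and the controls were littermates without Cre that also received tamoxifen. The 8 arrays formed 4 groups of 2: control and null at day 4 and at day 6. The label text conflicts for the null day 4 samples: their treatment text states 6 days, while their titles and characteristics state day 4, which was used here. Arrays are called null by their labels, since the Tcf4 signal did not check those labels.

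The deposited values are intensity, made by the authors as MAS5 signals on a linear scale, per the submitters' processing notes, with no MAS5 version stated. The 2% trimmed mean of every array was 250. The table held 45101 probe sets and no value at or below 0. A pseudocount of 6, the 10th percentile of all values, was added before log2. The array medians of log2 values spanned 0.789. A rule fixed before the data were examined made quantile normalization the main setting when this span was over 0.5, and no normalization an alternative. All group definitions, comparisons, thresholds, gene lists, the named-gene rule and most alternatives were also fixed before the data were examined. The 64 spike-in and control probe sets entered no test. Probe sets with a mean log2 value above the 40th percentile were kept, and each gene was represented by its brightest probe set among those naming exactly 1 gene, which gave 12696 genes. Genes were named from the platform table. Of the 34945 probe sets naming 1 gene, 34741 were matched by gene identifier to the RefSeq table of the GRCm38.p6 assembly, used only for current symbols and for X and Y membership. The files give no genome positions for probe sets, so no coordinates are given.

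Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend). All 8 arrays and 4 group means entered each fit, with 4 residual and 6.07 prior degrees of freedom. Calls used two-sided Benjamini-Hochberg adjusted p under 0.05. The 6 comparisons were null against control over both days, at day 4 and at day 6, the difference of these 2 null effects, and day 6 against day 4 in the control and in the null arrays. Errors of log2 changes of single genes are standard errors from limma, and errors of group levels are SD over 2 arrays. Errors of list and family means are standard errors over the member genes, which are not replicates, and do not measure the spread between arrays. The p-values measure only the spread between these arrays, which may be technical, since the labels do not say that the replicates are separate pools. In the fit itself, replicate 1 was set against replicate 2 within the groups in 8 contrasts, and limma called 0 genes in each, with 444 to 603 genes at unadjusted p under 0.05 against 635 by chance. Each contrast was judged against the other replicate differences of the same 4 groups, so few calls were likely by construction. It cannot show whether p-values between groups hold where pools, days or sexes differ. The fit was also tested on simulated data with 50 genes changed at each size: 26.0% were recovered at a 1.5-fold change, 44.0% at 2-fold, 78.0% at 3-fold and 80.0% at 4-fold, with 10 false among 124 calls. The simulated values were normal and independent between genes and arrays. Each gene had the same spread in all arrays, with no differences between days or pools. These figures describe such data and not the real arrays, where the null day 6 replicates were less alike than the others. Array number limits the precision.

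The 27 gene lists covered plasmacytoid and conventional dendritic cell genes (pDC identity, common, type 1 and type 2), MHC class II and class I presentation, nucleic acid sensing, interferon-stimulated genes, E-protein regulators, chemokine receptors and adhesion, a lymphoid program, the unfolded protein response, cell cycle, apoptosis, p53 damage response, early response and stress, cholesterol synthesis, oxidative phosphorylation and ribosomal proteins. Others held markers of B, plasma, T and NK cells, monocytes and macrophages, neutrophils, erythroid cells and platelets, and the sort gate. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 27 lists within a comparison. A list is said to be called, and to rise or fall, by this test unless another is named. Camera with an estimated correlation and fry were run beside it. Fry tests whether a list's genes move, on balance, one way, and does not compare them with other genes. With an estimated correlation, calls held for 2 of 7 lists over both days, 0 of 12 at day 4, 0 of 8 at day 6, 0 of 9 for the difference, 6 of 9 between the days in control and 9 of 13 in null. Some genes are in several lists: Cd83 is in the class II and the common dendritic lists, and Cd8a in the pDC and type 1 lists.

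Named genes are Tcf4 in every comparison, the 10 largest rises and 10 largest falls over both days among called genes with all 4 null arrays on one side of the 4 control arrays, up to 3 called members of each list with the smallest adjusted p, and the 5 largest rises and falls in each other comparison. For the lists of other cells and of the sort gate with no call, the 2 brightest members are given as levels. Other genes are named only as examples of a list and were chosen after their values were seen.

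The alternatives were other pseudocounts, filters, normalizations, probe set choices, spread estimates and replicate blocks, other thresholds, single days, models without or with an additive day term, and 1 array left out at a time. Chosen after the data were seen were the group means as samples, the fit without both day 6 arrays numbered 1, the results without X and Y genes, and the list tests with the mean of all probe sets or with median-centred arrays. Without normalization the median change of all genes was 0.11 at day 4, -0.13 for the difference and 0.10 between the days in control. Figures were drawn with matplotlib 3.10.9.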

Results

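Gene expression was measured on 8 arrays of plasmacytoid dendritic cells (pDC), the dendritic cell type specialised in type I interferon production, sorted from mouse spleen as CD11b-negative, B220-positive, CD11c-low and Bst2-positive cells. The control and the null group had 2 arrays each at day 4 and at day 6 after tamoxifen. The series asks how pDC change when the transcription factor E2-2 (gene Tcf4) is deleted in mature cells. The median MAS5 signal per array ran from 49.1 to 89.2, the highest in replicate 1 of null day 6, where the 10th percentile of signals was 17.8 against 4.47 to 6.58 in the other arrays. The correlation of the log2 signals of both replicates was 0.915 in null day 6 and 0.954 to 0.963 in the other groups. Replicate 2 of null day 6 correlated more with an array of another group (0.938) than with its own replicate, as no other array did. The ratio of 3 prime to 5 prime Gapdh probe sets, a sign of RNA length after amplification, was 23.0 to 42.5, and that for Actb 133 to 334. Detection values were not used here. Where a group's mean level lay at or below the highest array median of all probe sets (5.78 to 6.57 on the log2 scale) no fold is given, as that level is not shown to be above background and the log2 change then depends on the pseudocount. Changes of single genes below are log2 differences with their limma standard error, over 4 null and 4 control arrays or, for a single day, 2 and 2. The error of a list or family mean is the standard error over its genes.

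Null against control over both days asks which genes differed between the genotypes on the mean of both days, so that opposite effects of the days cancel. A mean over both days can also rest on a single day. It includes the null day 4 arrays, whose low Xist is described with day 4 below. Genes of MHC class II presentation rose in the null arrays: 12 of the 19 tested were called higher and 0 lower (13 and 1 adjusted over the list alone). The mean change was 0.57 ± 0.10. H2-DMb2 (probe set 1443687_x_at), a chain of the chaperone that loads peptide on class II, rose by 1.21 ± 0.06 (adjusted p = 4.92e-06). The class II beta chains H2-Eb1 (1417025_at, 1.03 ± 0.08) and H2-Ab1 (1450648_s_at, 0.77 ± 0.05) rose too, as did Cd83 (1416111_at, 1.49 ± 0.17), a marker of dendritic cell maturation. Other called members were H2-Ob, Cd40, a co-stimulatory receptor, Icam1, H2-DMa, Ctss, the protease that trims the invariant chain, Ifi30, Cd74 and H2-Oa, from 0.38 to 1.08, while the class II alpha chain H2-Aa was at 0.05 (adjusted p = 0.62). The list's adjusted p was 2.65e-13 with the preset and adjusted p = 0.0304 with an estimated correlation. Of its members, 7 were called higher at both days. One of 2 other H2-Ab1 probe sets lay at -0.72 and was not called.

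Early response and stress genes also rose, 11 of 27 higher and 0 lower (16 and 1 adjusted over the list alone), with a mean of 0.32 ± 0.09, adjusted p = 8.25e-09, and adjusted p = 0.0304 with an estimated correlation. The immediate early factor Fos rose by 0.93 ± 0.07 and Ier3 by 1.19 ± 0.10, with Dusp1, a MAP kinase phosphatase, at 0.91 ± 0.13 and Klf6 at 0.81 ± 0.11. The heat shock co-chaperone Dnajb1 rose by 0.56 ± 0.08, except without normalization (adjusted p = 0.0629), and its other probe set lay at -0.15.

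The pDC identity list held 5 higher and 12 lower of 38 genes (7 and 14 adjusted over the list alone), with a mean of -0.08 ± 0.08, adjusted p = 0.0443 and adjusted p = 0.187 with an estimated correlation. Cox6a2, a cytochrome oxidase subunit, fell by 0.72 ± 0.05 (1457633_x_at, adjusted p = 3.87e-05), the calcium-binding Nucb2 by 0.66 ± 0.05 on the log2 scale. The Fc receptor-like Fcrla was lower too, at 11.8 to 12.1 in the 4 null arrays against 12.8 to 13.3 in the 4 control arrays. Other called falls were Sla2 (-0.98 ± 0.10), Lifr, the leukaemia inhibitory factor receptor (-0.78 ± 0.12), Cdh1, Klk1, Dntt, Ccr9, Mctp2, Lair1 and Havcr1. The gut-homing chemokine receptor Ccr9 fell by 0.49 ± 0.04, and all 4 of its other probe sets were lower. For the probe set used, the change was -0.97 at day 4 and only -0.02 at day 6 (adjusted p = 0.865). Cd8a, which marks some pDC and type 1 conventional dendritic cells, rose by 1.49 ± 0.12 (adjusted p = 0.000122), with all 4 other probe sets higher. Ly6d, the interferon regulatory factor Irf8, Tspan31 and Klra17 were higher as well. The list's call was lost without either control day 4 array, replicate 1 of control day 6, replicate 2 of null day 4 or either null day 6 array (adjusted p = 0.0588 to 0.164), with the mean of all probe sets (-0.0547, 0.16) and with the group means as samples (0.186).

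Among the largest changes, the actin bundler Fscn1 (1416514_a_at), abundant in mature dendritic cells, rose 3.46-fold (1.79 ± 0.09, adjusted p = 4.92e-06), although its other probe set lay at -0.37. S100a4, a calcium-binding protein of motile cells, rose 3.91-fold (1.97 ± 0.20) and Nxpe4 3.17-fold (1.66 ± 0.16). The kallikrein Klk1b27 was 3.02-fold lower (-1.59 ± 0.10, adjusted p = 2.48e-05), followed by Bex1 (-1.42 ± 0.19), the ubiquitin ligase Mid1 (-1.33 ± 0.16) and the nucleoporin Nup54 (-1.28 ± 0.14). These 7 and Cd8a were called under each of the 11 alternatives run per gene. Those were a pseudocount of 1, no filter, no normalization and each array left out. They did not include median-centred arrays, the mean of all probe sets or a fit without the intensity trend. With the group means as samples, only S100a4, Fscn1 and Klk1b27 of these were called. The 2 other Nup54 probe sets lay at -0.27 and 0.085, neither called. The other 12 of the largest changes were less steady: Pcp2 (1.93), Lysmd2 (1.82), the B cell lectin Cd22 (1.67), Zfp33b (1.59), Zfp408 and the Y-linked Sry (1.53) were higher, and Abca4 (-2.21), Gm11190 (-1.87), Scrt1 (-1.71), the prostaglandin D synthase Ptgds (-1.55), Robo3 (-1.52) and Zfp385b (-1.44) lower. Each of these lost its call without at least 1 array (adjusted p = 0.0503 to 0.18), and between them every array but replicate 2 of null day 6 did so. Sry lost it also with a pseudocount of 1 (0.0516) and no filter on dim probe sets (0.0817).

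**Figure D1:**
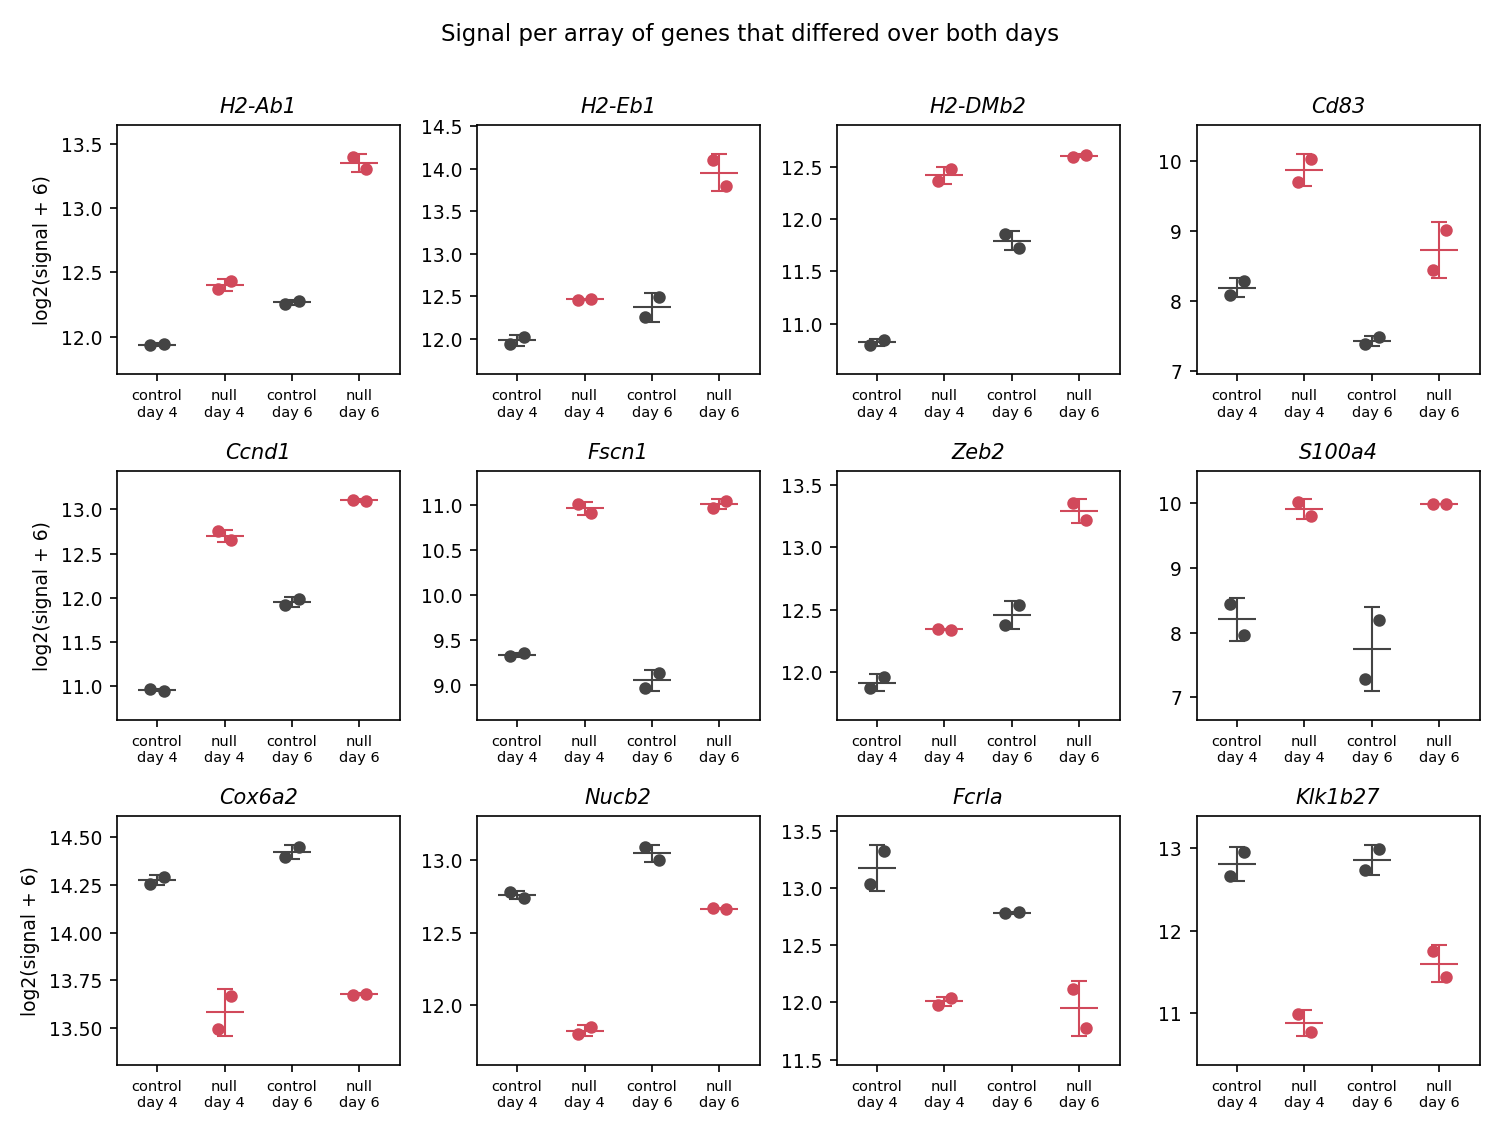
Quantile-normalized log2(signal + 6) of 12 genes, with 1 point per array and the mean and SD of each group of 2 (control grey, null red). In each panel both null arrays of a day lie on one side of both control arrays of that day, as for Fscn1, whose 2 control group means were 9.34 and 9.06, against array values of 10.9 or more in null.

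Several regulators moved. The E-protein regulator list rose, 6 higher and 1 lower of 33 (7 and 2 adjusted over the list alone), with a mean of 0.19 ± 0.08, adjusted p = 0.00729 and adjusted p = 0.227 with an estimated correlation. Zeb2, a repressor used in pDC and type 2 dendritic development, rose by 0.63 ± 0.06, but all 4 of its other probe sets lay between -0.42 and -0.14. Runx3 rose by 0.61 ± 0.10, with 1.08 at day 4 and 0.14 at day 6 (adjusted p = 0.617). Irf8 rose by 0.40 ± 0.06, a mean of opposite changes at day 4 and day 6. Class I presentation held 4 higher and 0 lower of 14 genes (5 and 0 adjusted over the list alone), with a mean of 0.16 ± 0.07, adjusted p = 0.0118 and adjusted p = 0.184 with an estimated correlation. Tapbp, the class I loading protein tapasin, rose by 0.62 ± 0.08, H2-K1 by 0.40 ± 0.06 and the immunoproteasome subunit Psmb8 by 0.38 ± 0.07, and 1 other H2-K1 probe set was called lower at -1.16. Psmb8 was not called without replicate 2 of control day 6 (0.0517) or replicate 1 of null day 4 (0.0531). Without replicate 2 of null day 6 neither list was called (both adjusted p = 0.0531), and class I was also lost without normalization (adjusted p = 0.104), with median-centred arrays (0.07, 0.373), with the mean of all probe sets (0.355) and with the group means as samples (0.198). Irf8 (0.27, adjusted p = 0.288), H2-K1 (0.33, 0.131) and Psmb8 (0.34, 0.0869) were not called without normalization.

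Camera called none of the lists in this paragraph, while fry called the common conventional dendritic list and the unfolded protein response upward (both adjusted p = 0.00809). In the cell cycle list 1 gene was higher and 2 lower of 34 (3 and 7 adjusted over the list alone, list adjusted p = 0.753). Cyclin D1, Ccnd1 (1448698_at), which drives entry into S phase, rose 2.73-fold (1.45 ± 0.06, adjusted p = 7e-07) with both other probe sets called higher. The replicative helicase genes Mcm4 (-0.79 ± 0.12) and Mcm2 (-0.54 ± 0.13) were lower. In oxidative phosphorylation 2 were higher and 5 lower of 29 (5 and 9 adjusted over the list alone, 0.597). Among these were Uqcrq (-0.57), Atp5pb (-0.36) and cytochrome c, Cycs (-0.38). Ribosomal proteins had 1 higher, Rpl8 (0.52), and 3 lower of 22 (1 and 3 adjusted over the list alone, 0.277), including Rpl11 (-0.60) and Rpl37 (-0.46). Common conventional dendritic genes had 3 higher and 1 lower of 23 (5 and 2 adjusted over the list alone, 0.204), with Ahnak at 0.32 and the inhibitory receptor Btla at -0.56. Type 1 genes had 3 and 3 of 17 (3 and 3 adjusted over the list alone, 0.68), with the adhesion molecule Cadm1 at -0.56 and Cd24a at -0.52. Type 2 genes had 4 and 2 of 21 (5 and 2 adjusted over the list alone, 0.155), with the lectin Clec10a at -0.47 and the cytokine Ltb at 0.84. Nucleic acid sensing had 2 and 2 of 21 (2 and 2 adjusted over the list alone, 0.503), with Ctsl, a protease that processes endosomal Toll-like receptors, at -0.46 and Ikbkg at -0.47. Interferon-stimulated genes had 0 and 2 of 29 (0 and 2 adjusted over the list alone, 0.183), the antiviral Rsad2 at -0.57 and Xaf1 at -1.90. Chemokine receptors and adhesion had 2 and 1 of 28 (3 and 3 adjusted over the list alone, 0.753), with the selectin ligand Selplg at 0.50 and Cd44 at 0.32, whose 2 other probe sets were negative. The lymphoid program had 3 and 3 of 17 (6 and 3 adjusted over the list alone, 0.733), with the interleukin 7 receptor Il7r at -0.47. The unfolded protein response had 3 and 2 of 23 (5 and 2 adjusted over the list alone, 0.204), with Herpud1 at 0.72, Dnajb9 at -0.39 and the translocon subunit Sec61b at -0.49. The p53 list had 0 and 1 of 21 (1 and 1 adjusted over the list alone, 0.967), Ccng1 at -0.64. Cholesterol synthesis had 0 and 1 of 16 (0 and 2 adjusted over the list alone, 0.273), Hmgcs1 at -0.28. Apoptosis had 0 and 0 of 22 (0 and 0 adjusted over the list alone, 0.753). The test pointed down where the mean was up for the cell cycle (0.03) and p53 (0.05) lists, as for NK cell genes (0.11), and the median differed in sign from the mean for oxidative phosphorylation and B cell genes. Mcm2, Ahnak, Btla, Ltb, Ikbkg, Selplg, Cd44 and Dnajb9 each lost the call without 1 or more arrays (0.0515 to 0.168), every array but replicate 2 of null day 6 among them. Hmgcs1 (adjusted p = 0.12), Rpl8 (0.0557), Cd44 (0.343), Ahnak (0.297) and Dnajb9 (0.0512) were not called without normalization. Several values in this paragraph average unlike days, given here as day 4 and then day 6. They include Xaf1 (-4.15, 0.36), Cd24a (-1.21, 0.18), Btla (-1.05, -0.08) and Il7r (-0.82, -0.13). Ctsl (-0.75, -0.17), Ccng1 (-0.98, -0.29), Atp5pb (-0.70, -0.025) and Ikbkg (0.07, -1.01) differed between the days as well.

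Markers of other cells differed too. Neutrophil genes fell, 0 higher and 3 lower of 13 (0 and 4 adjusted over the list alone), with S100a8 at -1.85, S100a9 at -1.30 and Camp at -0.76, adjusted p = 0.0126 and adjusted p = 0.184 with an estimated correlation. These values average opposite days: the list's mean was 0.50 at day 4, with 0 genes called, and -1.19 at day 6, and S100a8 was at 0.16 and -3.86. Erythroid and platelet genes fell, 0 and 3 of 13 (0 and 4 adjusted over the list alone), with the anion exchanger Slc4a1 at -0.52, Klf1 at -1.33 and Car1 at -1.52, adjusted p = 0.0112 and adjusted p = 0.184 with an estimated correlation. Camera called none of the other lists of this kind, while fry called monocyte and macrophage genes upward (adjusted p = 0.00353). Monocyte and macrophage genes had 2 and 1 of 21 (3 and 2 adjusted over the list alone, 0.173), with the scavenger receptor Cd163 at 1.20, Lgals3 at 0.39 and the growth factor receptor Csf1r, which was higher at day 4 and lower at day 6, at -0.33. B cell genes had 2 and 0 of 14 (3 and 1 adjusted over the list alone, 0.527), Cd22 and the kinase Blk (0.94). Plasma cell genes had 2 and 1 of 10 (2 and 1 adjusted over the list alone, 0.829), with Sdc1 at 0.57, Mzb1 at 0.30 and the immunoglobulin joining chain Jchain at -0.78. Mzb1 was at 1.07 at day 4 and -0.47 at day 6, and Jchain at 0.20 and -1.75. T cell genes had 0 and 1 of 10 (1 and 1 adjusted over the list alone, 0.262), Il7r. NK cell genes had 0 and 1 of 10 (0 and 1 adjusted over the list alone, 0.967), the receptor Klrd1, at 12.7 and 12.4 in null against 13.6 and 13.4 in control on the log2 scale. Of the sort gate, 0 of 3 were called (0 adjusted over the list alone, 0.493): Ptprc, which encodes B220, was at -0.05 ± 0.06 and Bst2 at 0.14 ± 0.06. The Ptprc value averages a fall at day 4 (-0.72) and a rise at day 6 (0.63). Camp, Slc4a1, Klf1, Car1, Lgals3, Csf1r, Cd22, Blk, Sdc1 and Mzb1 each lost the call without 1 or more arrays (0.0503 to 0.165), every array but replicate 2 of null day 6 among them. Csf1r (0.231), Mzb1 (0.192), Lgals3 (0.135), Car1 (0.104) and Klf1 (0.0629) were not called without normalization either. Without replicate 2 of null day 6 the neutrophil and erythroid lists were not called (both adjusted p = 0.0531).

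In all, 426 genes were higher and 396 lower of 12696. All 4 null arrays lay on one side of the 4 control arrays for 751 genes (5.92%), where chance gives 2.86% if all arrays are independent. Arrays of one group were alike, which can raise this share without an effect of the genotype. Of the 62 list members followed over both days, 38 were called under each of the same 11 alternatives run per gene. Limits are large: 405 genes were called without normalization (176 higher, 229 lower), 70 with median-centred arrays, 70 with an additive day term, 11 without the intensity trend, and 13 with the group means as samples. Without any 1 of the 4 day 4 arrays or the 2 control day 6 arrays the count was 413 to 458, and without replicate 2 of null day 6 it was 1573.

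Tcf4 itself, the targeted gene, was measured by 6 probe sets, with changes over both days from -0.28 to 0.26, and 0 of them passed the threshold when every probe set was tested. The files do not place these probe sets inside or outside the floxed part of the gene. An unchanged signal therefore does not show whether it was deleted. The brightest, 1434148_at, was at 0.26 ± 0.06 in the gene fit (adjusted p = 0.0387), at 0.06 ± 0.09 at day 4 (0.791) and at 0.47 ± 0.09 at day 6 (0.0112), a difference of 0.42 ± 0.13 (0.0634). Between the days it was at 0.02 ± 0.09 in control (0.942) and 0.44 ± 0.09 in null (0.0103). Its group means were 13.8 ± 0.08 and 13.8 ± 0.14 in control at day 4 and day 6, and 13.8 ± 0.16 and 14.2 ± 0.05 in null (SD, n = 2). At single days 1416723_at fell by 0.37 ± 0.09 at day 4 (0.0469) and 1434149_at by 0.57 ± 0.14 at day 6 (0.0409). The both-days call of 1434148_at was lost without normalization (0.14, adjusted p = 0.647) and without 6 of the arrays: either control array of day 4 (0.137, 0.061) or day 6 (0.051, 0.152), replicate 2 of null day 4 (0.13) or replicate 1 of null day 6 (0.0852). The day 6 call was lost without normalization (0.706), replicate 2 of control (0.112) or replicate 1 of null (0.0506), and the change between the days in null without normalization (0.943) or replicate 1 of null day 4 (0.0871).

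At day 4, null against control asks for the earlier effect. The null day 4 arrays had far less Xist than the other arrays, and their treatment text states 6 days. The sex of the mice and another time since tamoxifen therefore cannot be told apart from the genotype in this comparison. The results over both days, for the difference and between the days in null use these arrays and share this limit. Class II presentation rose, with 12 of 19 higher and 0 lower (14 and 0 adjusted over the list alone) and a mean of 0.70 ± 0.11, adjusted p = 1.55e-09 and adjusted p = 0.0611 with an estimated correlation. H2-DMb2 rose by 1.60 ± 0.09, Cd83 by 1.67 ± 0.24 and the invariant chain Cd74 by 0.88 ± 0.12. Early response genes rose as well, 12 and 0 of 27 (15 and 1 adjusted over the list alone), with a mean of 0.52 ± 0.11, adjusted p = 4.06e-06 and adjusted p = 0.0611 with an estimated correlation. Ier3 rose by 1.86 ± 0.15 and Fosb by 1.08 ± 0.16. The pDC identity list fell, 3 and 12 of 38 (5 and 12 adjusted over the list alone), with Lifr at -1.64 ± 0.17, Ccr9 at -0.97 ± 0.06, while Irf8 rose from 13.3 ± 0.01 in control to 14.8 ± 0.18 in null (SD, n = 2), adjusted p = 0.00559 and adjusted p = 0.114 with an estimated correlation. With the mean of all probe sets its mean went from -0.12 to -0.0422 and the call was lost (0.0904).

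E-protein regulators rose at day 4, 7 and 2 of 33 (10 and 3 adjusted over the list alone), with Irf8, Runx3 (1.08 ± 0.14) and Cbfa2t3 (0.96 ± 0.13), adjusted p = 0.0016 and adjusted p = 0.133 with an estimated correlation. The unfolded protein response rose, 4 and 0 of 23 (10 and 3 adjusted over the list alone), with Creld2 at 0.69 and Atf3 at 0.96, adjusted p = 0.0467 and adjusted p = 0.155 with an estimated correlation. Its call was lost without either control day 4 array, replicate 2 of null day 4 or either null day 6 array (0.0505 to 0.0763), with a replicate block within each day (0.0648) and with median-centred arrays (0.0833). Cell cycle genes fell, 1 and 8 of 34 (2 and 10 adjusted over the list alone), with the replication clamp Pcna at -1.34 and the nucleotide reductase Rrm2 at -1.45, adjusted p = 0.00599 and adjusted p = 0.174 with an estimated correlation, but not with the mean of all probe sets (0.0562). Cholesterol synthesis fell, 0 and 3 of 16 (0 and 4 adjusted over the list alone), with Idi1 at -1.12, adjusted p = 0.00599 and adjusted p = 0.133 with an estimated correlation. Oxidative phosphorylation fell, 0 and 7 of 29 (3 and 11 adjusted over the list alone), adjusted p = 0.00239 and adjusted p = 0.123 with an estimated correlation. Ribosomal proteins did too, 1 and 7 of 22 (2 and 11 adjusted over the list alone), adjusted p = 0.000127 and adjusted p = 0.0885 with an estimated correlation. Without normalization these 2 lists were not called (0.175 and 0.329), nor with median-centred arrays (0.157 and 0.261).

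Markers of other cells moved with these groups at day 4. Monocyte and macrophage genes rose, 7 and 1 of 21 (10 and 1 adjusted over the list alone), with a mean of 0.81 ± 0.19, the complement gene C1qb at 2.09 and Csf1r at 1.22, adjusted p = 0.000322 and adjusted p = 0.0885 with an estimated correlation. Plasma cell genes rose, 4 and 0 of 10 (8 and 0 adjusted over the list alone), with Mzb1 at 1.07, adjusted p = 0.000259 and adjusted p = 0.123 with an estimated correlation. Erythroid and platelet genes fell, 0 and 4 of 13 (1 and 4 adjusted over the list alone), with the carbonic anhydrase Car2 at -2.59 and the transferrin receptor Tfrc at -1.03, adjusted p = 0.0165 and adjusted p = 0.133 with an estimated correlation. Of the sort gate, 0 and 1 of 3 were called (0 and 1 adjusted over the list alone): Ptprc fell by 0.72 ± 0.08 (adjusted p = 0.000494), and the list was called downward by fry (0.018) but not by camera (0.0874).

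The X-inactivation RNA Xist was 111-fold lower in null day 4 (-6.80 ± 0.09, adjusted p = 6.24e-11, 2 of 2 arrays): its log2 signal was 8.24 and 7.94 there and 14.9 to 15.1 in the other 6 arrays. The Y-linked gene Eif2s3y was higher by 1.01 ± 0.27 (adjusted p = 0.037). Sry, called as well (0.0489), stood at only 4.42 and 4.86 on the log2 scale in control, where its change depends on the pseudocount. The other 4 Y-linked genes did not pass: Kdm5d was at 1.27 (0.102), Uba1y at 0.64 (0.683), Uty at 0.49 (0.673) and Orly at 0.26 (0.796). The phosphodiesterase Gdpd3 rose by 6.07 ± 0.14, from a dim level, and the interferon-stimulated Xaf1 fell by 4.15 ± 0.22 on the log2 scale. The other Xaf1 probe set was called lower too, at -1.14. Gdpd3 was low in control day 4 alone: in control it was higher by 5.37 at day 6, where null against control was at -0.19. Sgo1, which guards centromere cohesion, fell by 3.28 ± 0.52. The other named rises were Ppp1r3f (2.95), Ss18l1 (2.84), the vitamin transporter Slc5a6 (2.66) and the steroid hydroxylase Cyp21a1 (2.65), and the other falls the collagen Col4a4 (-3.68) and Bend6 (-3.40). Sgo1 and these 6 each lost the call without 1 or more arrays: Ppp1r3f without replicate 2 of null (0.0691), Sgo1 without either control (0.0505, 0.0524), and Col4a4 without either null array (0.126, 0.0758). So did Ss18l1, Bend6 and Cyp21a1 without any of the 4 day 4 arrays, and Slc5a6 without 3 of these or replicate 2 of control day 6 (0.0502 to 0.838). Without replicate 2 of null day 6 Cyp21a1 was at -0.03, from another probe set.

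At day 4, 662 genes were higher and 682 lower, and all 1344 had the arrays of both groups apart. So did 57.7% of the tested genes, where chance gives 33.3% if all arrays are independent. The count was 146 with median-centred arrays (48 higher, 98 lower), 65 without the intensity trend and 2167 with array weights. Without 1 of the 4 day 4 arrays it was 559 to 675.

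At day 6, null against control asks for the later effect. The pDC identity list, called downward at day 4, was not called there. Class II presentation rose again, 7 and 0 of 19 (9 and 0 adjusted over the list alone), with a mean of 0.44 ± 0.15, adjusted p = 2.12e-05 and adjusted p = 0.113 with an estimated correlation. H2-Eb1 rose by 1.58 ± 0.11, H2-Ab1 by 1.08 ± 0.07 and H2-Ob by 1.32 ± 0.19. Class I presentation rose, 4 and 0 of 14 (5 and 0 adjusted over the list alone), with H2-K1 at 0.80 ± 0.09 and Tapbp called too, adjusted p = 0.00157 and adjusted p = 0.113 with an estimated correlation, but not without normalization (0.0649), with the mean of all probe sets (0.156) or with median-centred arrays (0.32). Early response genes were called upward, 8 and 1 of 27 (10 and 2 adjusted over the list alone), with Fos at 1.14 ± 0.09, adjusted p = 0.00233 and adjusted p = 0.113 with an estimated correlation, and were not called without normalization (0.149) or with median-centred arrays (0.337).

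Cell cycle genes rose at day 6, 7 and 1 of 34 (10 and 2 adjusted over the list alone), with cyclin E, Ccne1, at 2.04, the topoisomerase Top2a at 1.55 and cyclin D2, Ccnd2, at -1.05, adjusted p = 0.0213 and adjusted p = 0.327 with an estimated correlation. That call was lost without replicate 2 of null day 6 (0.0994). Ribosomal proteins had 6 and 4 of 22 (7 and 4 adjusted over the list alone) and a mean of 0.09 ± 0.08, adjusted p = 0.0369 and adjusted p = 0.259 with an estimated correlation. Their direction turned without normalization (-0.24, adjusted p = 0.0354) and with median-centred arrays (-0.26, 0.32), and the call was lost without replicate 2 of control day 6 (0.221) or either null day 6 array (0.0778, 0.0994). The sort gate rose, 2 and 0 of 3 (3 and 0 adjusted over the list alone), with Ptprc at 0.63 and Bst2 at 0.36, adjusted p = 0.00262 and adjusted p = 0.138 with an estimated correlation, but not without normalization (0.0649) or with median-centred arrays (0.32). Beside these, neutrophil genes fell, 0 and 5 of 13 (0 and 6 adjusted over the list alone), with a mean of -1.19 ± 0.34, adjusted p = 2.12e-05 and adjusted p = 0.113 with an estimated correlation. Plasma cell genes fell, 0 and 4 of 10 (0 and 4 adjusted over the list alone), with Jchain at -1.75 ± 0.08, adjusted p = 0.00157 and adjusted p = 0.178 with an estimated correlation. Monocyte and macrophage genes, with a mean of -0.16, were called downward by fry (adjusted p = 0.0383) but not by camera (0.45). Csf1r was at -1.89 and Cd163 at 1.16.

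S100a8, a neutrophil calcium-binding protein, was 14.5-fold lower in null day 6 (-3.86 ± 0.11, adjusted p = 9.7e-08), and the myeloid lectin Clec4d fell by 3.50 ± 0.30 on the log2 scale. The adrenaline-synthesising enzyme Pnmt fell by 4.27 ± 0.47, and the chemerin receptor Cmklr1 was at -3.62 ± 0.64. The lymphoid factor Ets1 fell by 3.24 ± 0.13, and of its 3 other probe sets 1 was lower. The haem-binding Hebp1 rose by 3.23 ± 0.47 and the kinase Sgk1 by 2.92 ± 0.48, both from dim levels in control. Ankrd33 (3.14), the ubiquitin ligase Smurf1 (2.84) and Zfp33b (2.53) rose too. Cmklr1 was not called without replicate 2 of control day 6 (0.0765) nor Zfp33b without replicate 1. Ankrd33 and Smurf1 were not called without either control day 6 array, either null day 4 array or replicate 2 of control day 4, and Ankrd33 also not without replicate 1 (0.057 to 0.211).

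At day 6, 536 genes were higher and 538 lower, and all 1074 had the arrays of both groups apart. So did 48.1% of the tested genes, where chance gives 33.3% if all arrays are independent. The count was 646 without normalization (240 higher, 406 lower), 95 with median-centred arrays (29 higher, 66 lower), 52 without the intensity trend, 625 with array weights and 631 from the arrays of that day alone. Without either control day 6 array it was 450 and 471, and without replicate 2 of null day 6 it was 1909.

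**Figure D2:**
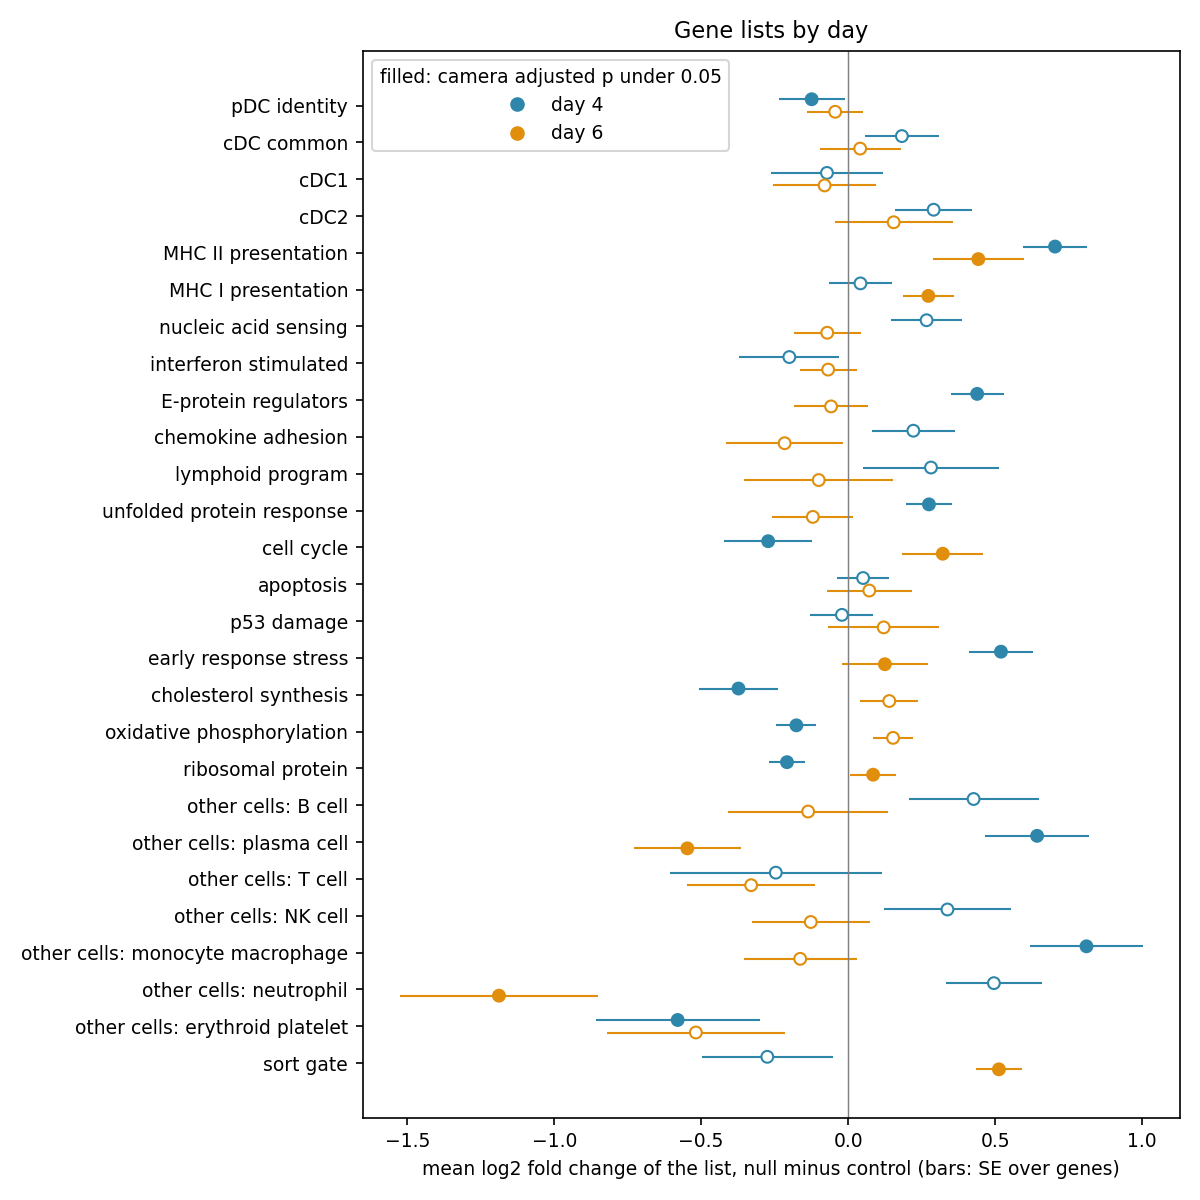
Mean log2 change of each of the 27 gene lists, null minus control, at day 4 (blue) and day 6 (orange), with bars for the standard error over the genes and filled points for an adjusted p under 0.05 by camera. MHC class II lies at 0.70 and 0.44, and neutrophil genes at 0.50 and -1.19, and plasma cell genes at 0.64 and -0.55; the positive day 6 value of ribosomal proteins was negative under both other scalings.

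The difference of the null effects, day 6 minus day 4, asks whether the effect differed between the days. Plasma cell genes moved down in this contrast, 0 and 6 of 10 (0 and 8 adjusted over the list alone), with a mean of -1.19 ± 0.27, Jchain at -1.96 ± 0.11, adjusted p = 3.17e-05 and adjusted p = 0.14 with an estimated correlation. Neutrophil genes, 0 and 5 of 13 (0 and 7 adjusted over the list alone), had a mean of -1.68 ± 0.30, adjusted p = 3.17e-05 and adjusted p = 0.14 with an estimated correlation. Monocyte and macrophage genes, 1 and 6 of 21 (1 and 7 adjusted over the list alone), had a mean of -0.97 ± 0.30, with Csf1r at -3.11 ± 0.15, adjusted p = 0.00498 and adjusted p = 0.14 with an estimated correlation. Irf8 went from a rise at day 4 to a fall at day 6, a difference of -2.21 ± 0.13 (adjusted p = 8.5e-06). Class II presentation had 2 and 2 of 19 (2 and 4 adjusted over the list alone) and was not called (adjusted p = 0.257).

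Upward in this contrast were cell cycle genes, 7 and 2 of 34 (11 and 4 adjusted over the list alone), with Rrm2 at 2.34 ± 0.18, adjusted p = 0.00237 and adjusted p = 0.166 with an estimated correlation. Cholesterol synthesis had 4 and 0 of 16 (6 and 0 adjusted over the list alone), adjusted p = 0.0138 and adjusted p = 0.166 with an estimated correlation, and was not called without replicate 2 of null day 4 (0.0599), with the mean of all probe sets (0.0572) or with median-centred arrays (0.0671). Oxidative phosphorylation had 8 and 0 of 29 (11 and 1 adjusted over the list alone), adjusted p = 0.00309 and adjusted p = 0.14 with an estimated correlation, but was not called without normalization (0.951) or with median-centred arrays (0.521). Ribosomal proteins had 6 and 2 of 22 (11 and 3 adjusted over the list alone) and a mean of 0.29, adjusted p = 0.000222 and adjusted p = 0.14 with an estimated correlation, and turned to -0.18 without normalization and -0.10 with median-centred arrays. The pDC identity list had 13 and 4 of 38 (15 and 6 adjusted over the list alone), with Lifr at 1.73 ± 0.24 and Ccr9 at 0.94 ± 0.09, adjusted p = 0.0395 and adjusted p = 0.166 with an estimated correlation. It was not called without normalization (mean -0.04, adjusted p = 0.527), with the mean of all probe sets (mean -0.0250, 0.505), with median-centred arrays (0.521), with a replicate block within each day (0.0647), or without replicate 2 of control day 6 (0.0818), replicate 2 of null day 4 (0.0951) or replicate 1 of null day 6 (0.0779). The sort gate had 2 and 0 of 3 (2 and 0 adjusted over the list alone), with Ptprc at 1.34 ± 0.11, adjusted p = 0.00498 and adjusted p = 0.14 with an estimated correlation, and was not called with median-centred arrays (0.126) or with no filter on dim probe sets (mean 0.17 against 0.79, adjusted p = 0.0911).

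Xist (6.95 ± 0.13), Xaf1 (4.50 ± 0.31) and Sgo1 (4.97) had upward differences called under each of the 11 alternatives. Bend6 (5.21) and Tbpl1 (4.50), a relative of the TATA-binding protein, had less steady ones. Downward were Gdpd3 (-6.25 ± 0.19), the immunoglobulin chain Ighg3 (-5.08 ± 0.40), Pnmt (-4.97 ± 0.66), Cmklr1 (-4.59) and the lens protein Grifin (-4.31). Bend6 was not called without replicate 1 of control day 4 (0.0702) or of null day 6 (0.0656), Grifin without replicate 1 of control day 4 (0.0948) or normalization (0.0501), and Cmklr1 without replicate 2 of control day 6 (0.0505) or of null day 4 (0.0522). Tbpl1 was not called without any 1 day 4 array or replicate 2 of null day 6 (0.0577 to 0.114). In all, 796 genes were called upward and 754 downward. Of the genes called at day 4, 67 were higher and 48 lower at both days, where independent calls would give 28.0 and 28.9. Another 141 went from higher to lower and 135 from lower to higher, where 28.1 and 28.8 are given. Both days used the same spread estimate of each gene, so their calls are not independent even without a shared effect. All of these counts lay above independence, and the excess alone does not show shared or opposite effects. Opposite calls did outnumber those in the same direction. Across the 12696 genes, which are not independent replicates, the effects of the days correlated at r = -0.109 (Spearman's rho = -0.127). The correlation was -0.134 without replicate 1 and -0.0489 without replicate 2 of null day 6, and -0.0694 with no filter on dim probe sets. The count was 263 with median-centred arrays and 100 without the intensity trend. Without 1 array it was 864 to 1005 for each of the day 4 and control day 6 arrays, where replicate 2 of control day 4 gave 1005, and higher, at 2315, without replicate 2 of null day 6.

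Day 6 against day 4 in the control arrays compares the days without the deletion. The days were different samples. Other cells in the sorted samples, or a batch, therefore cannot be told apart from a change of the pDC with time. Genes of monocytes and macrophages fell, 0 higher and 13 lower of 21 (0 and 16 adjusted over the list alone), with a mean of -2.07 ± 0.29, the adhesion molecule Vcam1 at -4.59 ± 0.19 and C1qb at -4.42 ± 0.42, adjusted p = 3.73e-15 and adjusted p = 0.0229 with an estimated correlation. Cell cycle genes fell, 1 and 19 of 34 (2 and 24 adjusted over the list alone), with a mean of -1.43 ± 0.27, Cdc20 at -3.71 ± 0.14 and the proliferation marker Mki67 at 9.44 on day 4 and 7.44 on day 6, adjusted p = 5.06e-15 and adjusted p = 0.0245 with an estimated correlation, while Ccnd1 rose by 0.99 ± 0.08. Erythroid and platelet genes fell, 0 and 7 of 13 (0 and 10 adjusted over the list alone), with the haem synthase Alas2 at -3.04, adjusted p = 2.14e-08 and adjusted p = 0.0245 with an estimated correlation. Neutrophil genes fell, 0 and 6 of 13 (0 and 8 adjusted over the list alone), with S100a8 at -2.82 ± 0.11, adjusted p = 7.09e-09 and adjusted p = 0.0245 with an estimated correlation. The pDC identity list rose, 12 and 2 of 38 (13 and 4 adjusted over the list alone), with a mean of 0.23 ± 0.08, Siglech, a pDC lectin, at 0.51 ± 0.09, the nucleic acid sensor Tlr7 at 0.45 ± 0.12 and Irf8 at 1.44 ± 0.09, adjusted p = 0.000105 and adjusted p = 0.0419 with an estimated correlation, but not with median-centred arrays (0.216).

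Class II presentation rose in control too, 8 and 1 of 19 (10 and 2 adjusted over the list alone), with Cd74 at 0.82, adjusted p = 2.47e-05 and adjusted p = 0.0499 with an estimated correlation, just under the threshold. Nucleic acid sensing rose, 4 and 0 of 21 (9 and 0 adjusted over the list alone), with the endosomal sensor Tlr9 at 1.75 ± 0.40, adjusted p = 0.000221 and adjusted p = 0.11 with an estimated correlation. Early response genes fell, 1 and 6 of 27 (2 and 8 adjusted over the list alone), with Egr1 at -1.58, adjusted p = 0.0116 and adjusted p = 0.11 with an estimated correlation, but not with the mean of all probe sets (0.153). Oxidative phosphorylation fell, 2 and 5 of 29 (2 and 9 adjusted over the list alone), adjusted p = 0.0138 and adjusted p = 0.166 with an estimated correlation, but not without normalization (0.292) or with median-centred arrays (0.275). The largest falls were Car2 (-6.01 ± 0.43), the erythroid gene Hemgn (-5.68 ± 0.42), Rrm2 (-4.80 ± 0.13), Ccne1 (-4.78 ± 0.51) and the lactate transporter Slc16a1 (-4.66 ± 0.60). Gdpd3 rose by 5.37 ± 0.14. It was followed by the calcium sensor Casr (3.33), Ttc34 (3.24), Prr15l (3.09) and Ss18l1 (2.96). Gdpd3 and Ss18l1 were also higher in null than in control at day 4, so control day 4 was the low group of both comparisons. Casr was not called without either control day 4 array, and Ttc34, Prr15l and Ss18l1 without any 1 of the 4 control arrays (0.0523 to 0.156).

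In control, 487 genes were higher and 618 lower at day 6, and all 1105 had the arrays of both days apart. So did 55.1% of the tested genes, where chance gives 33.3% if all arrays are independent. The count was 667 without normalization (225 higher, 442 lower), 272 with median-centred arrays (28 higher, 244 lower), 168 without the intensity trend, 1693 with array weights and 626 with a replicate block within each day. Without 1 of the 4 control arrays it was 414 to 505, and without replicate 2 of null day 6 it was 1599.

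Day 6 against day 4 in the null arrays makes the same comparison in the null group, with the same limit. Neutrophil genes fell, 0 and 12 of 13 (0 and 12 adjusted over the list alone), with a mean of -3.25 ± 0.48 and S100a8 115-fold lower (-6.84 ± 0.11), adjusted p = 5.55e-13 and adjusted p = 0.0174 with an estimated correlation. Monocyte and macrophage genes fell, 2 and 14 of 21 (2 and 17 adjusted over the list alone), with a mean of -3.04 ± 0.52, adjusted p = 5.55e-13 and adjusted p = 0.0174 with an estimated correlation. Csf1r was 103-fold lower (-6.69 ± 0.11) and the transglutaminase Tgm2 94.0-fold (-6.56 ± 0.24). Other probe sets gave smaller falls: -4.94 and -2.69 for Csf1r, both called, and -5.76 to -0.20 for Tgm2, 2 of 4 called. C1qb (-7.26 ± 0.42) and Vcam1 (-6.53 ± 0.19) fell to dim levels, 5.72 and 5.83 on the log2 scale. The other C1qb probe set was called at -6.09, while the 2 others of Vcam1 lay at -2.54 and -1.39, neither called. Plasma cell genes fell, 1 and 8 of 10 (1 and 9 adjusted over the list alone), with Jchain at -2.89 ± 0.08, adjusted p = 2.37e-07 and adjusted p = 0.0444 with an estimated correlation. Erythroid and platelet genes fell, 1 and 10 of 13 (1 and 10 adjusted over the list alone), with Slc4a1 at -3.43 ± 0.14, adjusted p = 8.6e-06 and adjusted p = 0.0444 with an estimated correlation.

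The pDC identity list rose in null, 18 and 4 of 38 (18 and 4 adjusted over the list alone), with a mean of 0.31 ± 0.09, Bst2 at 0.87 ± 0.09 and Siglech at 0.55 ± 0.09, adjusted p = 2.3e-07 and adjusted p = 0.0257 with an estimated correlation. Irf8 was at -0.77 ± 0.09. The sort gate rose, 3 and 0 of 3 (3 and 0 adjusted over the list alone), with Ptprc at 1.07 ± 0.08, adjusted p = 8.69e-05 and adjusted p = 0.0444 with an estimated correlation. Class I presentation rose, 6 and 0 of 14 (7 and 0 adjusted over the list alone), with H2-K1 at 0.82 ± 0.09, adjusted p = 0.000118 and adjusted p = 0.0444 with an estimated correlation, but not with median-centred arrays (0.074). Early response genes fell, 5 and 13 of 27 (5 and 15 adjusted over the list alone), with Egr1 at -2.14 ± 0.16 and Atf3 at -1.65 ± 0.24, adjusted p = 0.0011 and adjusted p = 0.0497 with an estimated correlation. Cell cycle genes fell, 1 and 10 of 34 (1 and 17 adjusted over the list alone), with Rrm2 at -2.46 ± 0.13, adjusted p = 6.26e-06 and adjusted p = 0.0591 with an estimated correlation.

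Cholesterol synthesis rose in null, 7 and 0 of 16 (8 and 0 adjusted over the list alone), with the farnesyl synthase Fdps at 2.31 ± 0.55, adjusted p = 0.00652 and adjusted p = 0.102 with an estimated correlation. Ribosomal proteins had 12 and 3 of 22 (15 and 3 adjusted over the list alone) and a mean of 0.27, adjusted p = 9.27e-06 and adjusted p = 0.0444 with an estimated correlation. Oxidative phosphorylation had 7 and 5 of 29 (12 and 5 adjusted over the list alone) and a mean of 0.18, adjusted p = 0.00572 and adjusted p = 0.102 with an estimated correlation. Both turned negative without normalization (-0.08 and -0.06) and with median-centred arrays (-0.11 and -0.09), and oxidative phosphorylation was not called without replicate 2 of null day 4 (0.052). Class II presentation had 5 and 2 of 19 (6 and 3 adjusted over the list alone) and a mean of 0.06 ± 0.19, adjusted p = 0.0401 and adjusted p = 0.176 with an estimated correlation. It was not called without normalization (-0.05, 0.663), with median-centred arrays (-0.08, 0.839), with a replicate block within each day (-0.07, 0.116), without replicate 1 of null day 4 (0.0594) or without replicate 2 of null day 6 (-0.07, 0.299). Xist rose 125-fold (6.96 ± 0.09), Xaf1 by 3.78 ± 0.22 and 9230114K14Rik by 3.31 ± 0.63, the last 2 from dim levels. The other Xaf1 probe set lay at 0.38 and was not called. The deacetylase Hdac11 (3.61) and Myo1h (3.58) were not called without either null day 4 array, nor Hdac11 without replicate 1 of null day 6 (0.0637 to 0.212).

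In null, 854 genes were higher and 979 lower at day 6, and all 1833 had the arrays of both days apart. So did 52.6% of the tested genes, where chance gives 33.3% if all arrays are independent. The count was 538 with median-centred arrays (124 higher, 414 lower), 655 without the intensity trend and 2837 with every probe set. Without either null day 4 array it was 995 and 920.

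**Figure D3:**
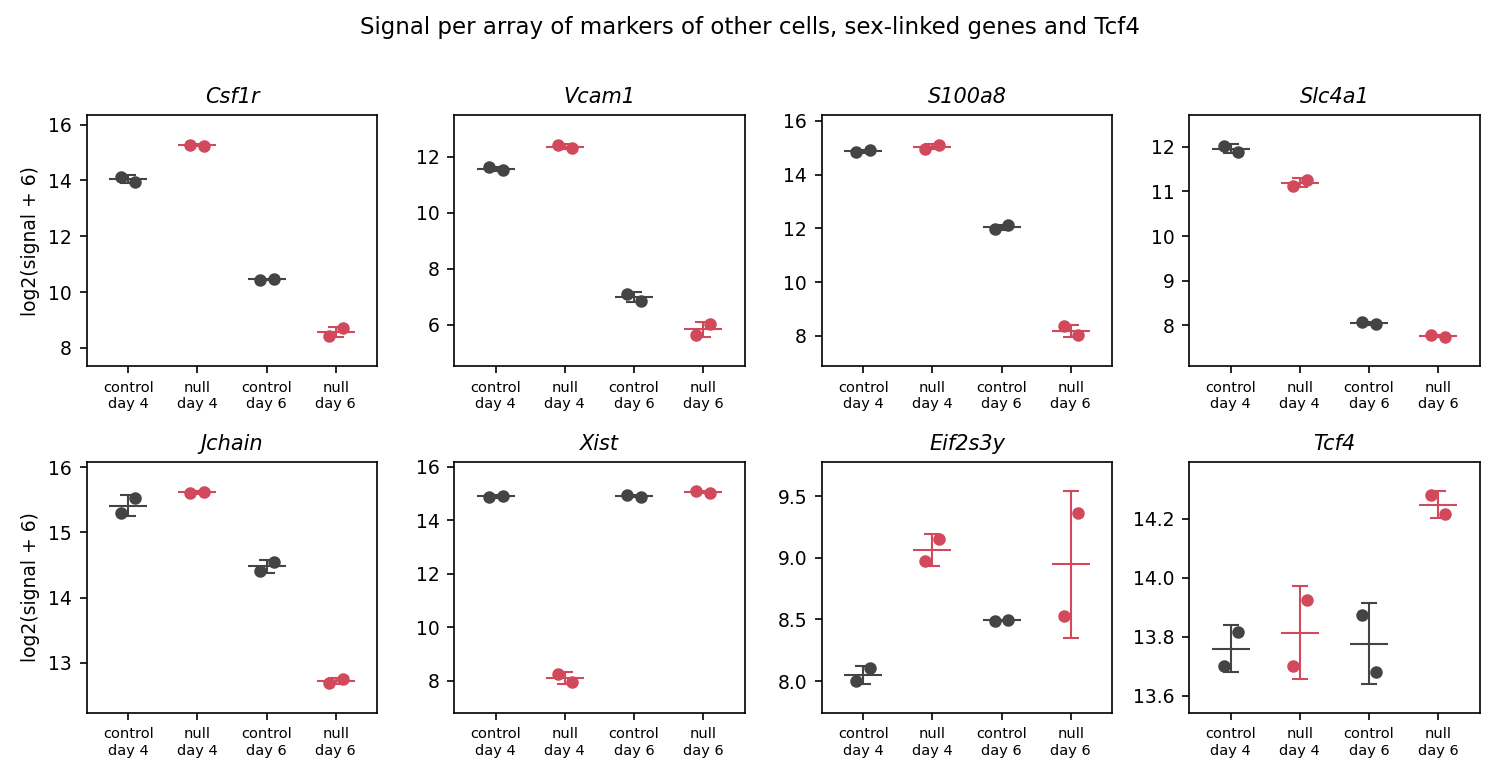
Quantile-normalized log2(signal + 6) of 8 genes, with 1 point per array and the mean and SD of each group of 2 (control grey, null red): macrophage genes Csf1r and Vcam1, neutrophil S100a8, erythroid Slc4a1, plasma cell Jchain, sex-linked Xist and Eif2s3y, and Tcf4. The 5 markers of other cells were lower at day 6 than at day 4 in both genotypes, and Xist stands at 8.24 and 7.94 in null day 4 alone.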

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

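The tests of the markers of other cells, of the sex chromosomes and of the day 6 array with high dim signals were chosen after the results they weigh were seen; the splits of the arrays, the test without genes of other blood cells and both probe set tests were planned ahead.

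The null effect differed between day 6 and day 4 in 1550 genes by limma, and in 54 of the 116 named genes, 26 upward and 28 downward, which is what drew attention to them. The values are day 6 effect minus day 4 effect, on the log2 scale. Irf8 went from a rise to a fall (-2.21), while class II genes split, H2-Eb1 (1.10) and H2-Ab1 (0.62) being larger at day 6 and H2-DMb2 (-0.78) at day 4. Class I genes H2-K1 (0.80) and Tapbp (0.76) were larger at day 6. Upward too were the dendritic and lymphoid genes Cd24a (1.40), Btla (0.98), Ccr9 (0.94), Il7r (0.69), Ly6d (0.65), Nucb2 (0.55), Ctsl (0.58) and Bst2 (0.46), with Ptprc (1.34), Ccng1 (0.70), Atp5pb (0.68), Hebp1 (3.33), Xist (6.95), Xaf1 (4.50), Bend6 (5.21), Sgo1 (4.97) and Tbpl1 (4.50). Car2 (4.0), Slc16a1 (3.97), Ccne1 (2.80), Rrm2 (2.34) and Hemgn (2.27) were upward as well, while the erythroid and platelet list was not called for the difference (mean 0.06, camera adjusted p = 0.624). Downward were the myeloid genes S100a8 (-4.02), S100a9 (-3.01), Clec4d (-3.61), Csf1r (-3.11), Tgm2 (-3.19), C1qb (-2.84), Camp (-2.56), Vcam1 (-1.94) and Lgals3 (-0.79), and the plasma cell genes Ighg3 (-5.08), Jchain (-1.96) and Mzb1 (-1.54). So were Gdpd3 (-6.25), Pnmt (-4.97), Cmklr1 (-4.59), Grifin (-4.31), Ss18l1 (-4.23), Ets1 (-3.95), Slc5a6 (-3.34), Ppp1r3f (-3.03), Ier3 (-1.35), Ikbkg (-1.07), Runx3 (-0.94), Ccnd1 (-0.60), Sec61b (-0.53) and Rsad2 (-0.46). With 2 arrays per group, no array could be tested for standing apart from its group.

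The count of genes changed over both days was set against all 35 splits of the 8 arrays into 4 and 4, in a fit with no day term. The genotypes gave 10 genes (1060 at unadjusted p under 0.05), and 3 of the 35 splits gave at least as many, so chance cannot be excluded for this count. The split by day gave 217 (1606), the highest of the others, and that of control of one day with null of the other 58, with the most genes of all splits at unadjusted p under 0.05 (1985). Both point to structures of the arrays larger than the genotype, by day and by the combination of day and genotype. Splits that divided the groups gave 0 genes by limma, with at most 867 at unadjusted p under 0.05. With the day as an additive term the genotypes gave 70 genes.

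Class II presentation genes were higher in the null arrays at both days. If conventional dendritic cells, monocytes and macrophages, or B cells in the pools were the only source, their own markers would be expected to rise. How far depends on the level of these markers in the pDC, and some are shared, such as Irf8 and Cd8a of the type 1 list. At day 6 the class II mean exceeded that of the markers by 0.401 for conventional dendritic cells of every type (95% bootstrap interval over genes 0.045 to 0.747, 59 genes). It did so by 0.606 for monocytes and macrophages (0.138 to 1.07, 21 genes) and by 0.579 for B cells (0.00855 to 1.16, 14 genes). The intervals take genes as independent, which they are not. Monocyte and macrophage markers did not rise at day 6 (mean -0.163), which argues against these cells as the single source at that day. For conventional dendritic cells the test cannot decide, since their lists share genes with pDC. The type 2 markers alone rose less than class II at day 4, by 0.413 (0.0829 to 0.74, 21 genes), but at day 6 the difference was 0.288 (-0.186 to 0.778), with type 2 and class II medians of 0.38 and 0.41. Cells of type 2 as the source therefore cannot be told apart there. Fry, which tests against no change, called the common dendritic list upward at day 6 (adjusted p = 0.0121), with Cd83 in it. Without class II list members the common markers were at -0.016, below class II by 0.459 (0.0723 to 0.849). For B cells the lower bound at day 6 lay close to no difference. Their difference was 0.278 at day 4 (-0.187 to 0.765) and 0.428 over both days (-0.0207 to 0.876), so B cells as a part or the whole stay open. At day 4 the same difference was 0.586 for conventional dendritic cells but -0.107 for monocytes and macrophages (-0.509 to 0.328). For the latter it was 0.25 over both days (-0.0431 to 0.545), and C1qb was up by 2.09 at day 4. Macrophage RNA may thus have added to the rise there, although the sort took CD11b-negative cells. The gate also took only CD11c-low and Bst2-positive cells, and whether type 2 or B cells passed it was not tested. Loss of E2-2 in the pDC, a different source on each day, and the Cre recombinase itself, which only the null mice carried, stay open and were not tested. At day 4 the null pools also differed from the rest in Xist, and their treatment text states 6 days. The sex of these mice and another time since tamoxifen cannot be told apart from the genotype there.

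The null effects of day 4 and day 6 ran opposite to each other across genes, weakly. The array with high dim signals, replicate 1 of null day 6, is not the source alone, since r was -0.134 without it. Without replicate 2 of that group r was only -0.0489, so much of the opposition rested on that array. Another test left out genes called between the days in control and genes on the lists of other blood cells, plasma cells and the cell cycle. Across the 11549 genes left, r was -0.0772 (SD 0.0231 over arrays left out). Opposite calls went from 141 and 135 to 103 in all, and same-direction calls from 67 and 48 to 70 in all. Genes of other blood cells that were not called in control stayed in. The test therefore cannot decide whether those cells were the whole cause. Without the genes on the X and Y chromosomes r was -0.107, so it did not rest on those genes. They were only 3.27% of the tested genes, too few to move r much. The test therefore says nothing on the sex of the mice, and Xist shows that the null day 4 pools differed from the rest. Other blood cells, the sex of these mice acting on other genes, other differences between single pools, and a true change with time since tamoxifen stay open. Each group was 2 arrays.

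Probe sets of one gene often disagreed: over both days 356 of 544 second probe sets (65.4%) had the sign of the called change, against 54.8% for all genes. At day 4 it was 76.0%, against 59.9% for all genes, and at day 6 only 56.4%, against 52.5%. With those marked as able to bind other transcripts left out it was 64.0% (95% interval 58.3 to 69.4, 300 probe sets), which argues against cross-binding of that kind as the main source. Among the brightest of 3 equal sets by signal it was 72.4% (65.3 to 78.7, 181 probe sets), against 58.8% among the dimmest, so noise of dim probe sets may be part of it and cannot be told apart from other sources. Transcripts with other 3 prime ends and losses in 2 rounds of amplification were not tested.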

How the results depend on the processing

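The group means as samples, the fit without both day 6 arrays numbered 1, the results without X and Y genes, and the list tests on means of all probe sets or with median-centred arrays were chosen after the data were seen. Counts of called genes depended strongly on the setting, and the cause was not tested unless named. Over both days (822 genes) they were 405 without normalization, 70 with median-centred arrays, 293 with the mean of all probe sets, 11 without the intensity trend, 303 at adjusted p under 0.01, 92 with a 2-fold change, 10 with no day term, 70 with day as an additive term, 536 without both day 6 arrays numbered 1 and 13 with the group means. At day 4 (1344) they were 146 with median-centred arrays, 620 with the mean of all probe sets, 65 without the intensity trend, 2167 with array weights, 610 at adjusted p under 0.01 and 364 with a 2-fold change. At day 6 (1074) they were 646 without normalization, 95 with median-centred arrays, 301 with the mean of all probe sets, 1661 with every probe set, 52 without the intensity trend, 625 with array weights, 426 at adjusted p under 0.01, 322 with a 2-fold change and 631 from that day's arrays alone. For the difference (1550) they were 263, 638, 2414 and 100 with median-centred arrays, the mean of all probe sets, every probe set and no intensity trend, then 710 at adjusted p under 0.01 and 889 with a 2-fold change. Between the days in control (1105) they were 667 without normalization, 272 with median-centred arrays, 501 with the mean of all probe sets, 168 without the intensity trend, 1693 with array weights, 626 with a replicate block within each day, 438 at adjusted p under 0.01 and 344 with a 2-fold change. In null (1833) they were 538, 969, 2837 and 655 with median-centred arrays, the mean of all probe sets, every probe set and no intensity trend, then 913 at adjusted p under 0.01 and 735 with a 2-fold change. The stricter thresholds lower a count, and every probe set raises the number tested, by construction. With 1 array left out the counts ran from 413 (without replicate 1 of control day 6) to 1573 over both days, 559 (replicate 1 of control day 4) to 1974 at day 4, 450 (replicate 1 of control day 6) to 1909 at day 6, 864 (replicate 1 of control day 4) to 2315 for the difference, 414 (replicate 2 of control day 6) to 1599 in control and 920 (replicate 2 of null day 4) to 2695 in null, each highest value without replicate 2 of null day 6. A group left with 1 array was assumed to vary like the others. A replicate block over all groups gave 749, 1282, 1019, 1499, 1049 and 1770 in the same order, and the correlation of equally numbered replicates between groups was 0 to 0.016 over 6 pairs, so numbers showed no pairing. The correlation of the day effects was -0.0694 with no filter on dim probe sets, and -0.134 to -0.0489 with 1 array left out (replicates 1 and 2 of null day 6). Class II presentation and early response kept direction and call over both days in every setting run, with means of 0.49 to 0.64 and 0.26 to 0.36. Directions turned for ribosomal proteins at day 6 without normalization (-0.24) and with median-centred arrays (-0.26), for their difference (-0.18 and -0.10) and in null (-0.0808 and -0.11), for oxidative phosphorylation in null (-0.0622 and -0.0944), and for Cyp21a1 at day 4 (-0.0281 without replicate 2 of null day 6 to 2.99 without replicate 1 of control day 4), where without the former another probe set became the brightest. Small list means also turned, with the call lost: pDC identity for the difference (-0.0419 without normalization, -0.0250 with the mean of all probe sets) and class II in null (-0.0499 without normalization, -0.0660 with a replicate block within each day, -0.0733 without replicate 2 of null day 6, -0.0821 with median-centred arrays). Of 137 single-gene results, 77 kept direction and side of the threshold in all settings run, as did 83 of 162 list results. Dim signals limit detection: the 10th percentile of signals was 17.8 in replicate 1 of null day 6 and 4.47 in replicate 2.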

Other observations

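All family tests in this part were chosen after the data were seen.

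Tuba1a, an alpha-tubulin of microtubules, rose over both days (0.74 ± 0.05, adjusted p = 3.87e-05) and at each of them, 0.71 at day 4 and 0.77 at day 6. The beta-tubulin Tubb2b rose by 0.57 at day 4 (adjusted p = 0.0378) and fell by 1.83 at day 6 (0.000104). Of 12 tubulins 4 were higher and 0 lower at day 4, with a mean of 0.51 ± 0.23, adjusted p = 0.0455 over 22 families and adjusted p = 0.289 with an estimated correlation. At day 6 the family had 1 higher and 2 lower, with a mean of -0.46 ± 0.19 (adjusted p = 0.388), and the difference was not called (-0.97 ± 0.32, 0.0697). Proteasome subunits moved the other way at day 4, 2 higher and 10 lower of 39, with Psma7 at -0.74 and the immunoproteasome subunit Psmb8, also on the class I list, at 0.60, adjusted p = 0.0455 and adjusted p = 0.289 with an estimated correlation. Small nuclear ribonucleoproteins, which form the splicing machinery, had 0 higher and 5 lower of 19 at day 4, with a mean of -0.21 ± 0.08, adjusted p = 0.037 and adjusted p = 0.289 with an estimated correlation. For the difference, day 6 minus day 4, they had 5 higher and 0 lower (0.31 ± 0.10, adjusted p = 0.0308, and adjusted p = 0.318 with an estimated correlation). Over both days and at day 6 camera called none of the 22 families, and the lowest adjusted p over both days was 0.187 for the kallikrein 1 group, with 0 higher and 2 lower of 8 and a mean of -0.39 ± 0.27.

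Between the days in the null arrays, chemokines fell, 0 higher and 4 lower of 18, with a mean of -1.01 ± 0.37 and adjusted p = 0.0256, and Gimap GTPases of lymphocyte survival fell, 0 and 3 of 8, with a mean of -0.89 ± 0.28 and adjusted p = 0.038. Tubulins fell as well, 0 and 3 of 12, with a mean of -0.76 ± 0.22 and adjusted p = 0.0256. Translation initiation factors had 13 higher and 2 lower of 45, adjusted p = 0.033, and cathepsins 7 and 2 of 14 (0.0362). S100a proteins (-1.55 ± 0.92, 0.0256) and Clec lectins (-1.22 ± 0.53, 0.042) fell, as they did in control (-0.56, 0.0224, and -0.83, 0.041), beside the neutrophil (-3.25) and monocyte and macrophage (-3.04) lists, whose kind of genes, such as S100a8 and Clec4d, these families hold. In control the small nuclear ribonucleoproteins fell too, 0 and 5 of 19 (-0.14 ± 0.10, 0.041). None of these calls in null held with an estimated correlation (adjusted p = 0.176 to 0.185), nor those in control (0.297). The families were not run under the other scalings.

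Across genes, which are not independent replicates, the change from day 4 to day 6 in control and in null correlated at r = 0.162 (0.125 to 0.162 with 1 array left out).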
